A study of Mus musculus with 9 samples.

How the data were processed

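Gene expression was measured by RNA-seq in wild-type mouse brain microvascular endothelial cells, given as a cell line in the labels. The 9 libraries form 9 groups of 1: normoxia, oxygen-glucose deprivation without serum (OGD), and OGD with 3 µM obacunone (OGD+Oba), each at 1, 3 and 6 h. RNA was extracted with a column kit and sequenced on a DNBSEQ instrument. The submitters' notes name HISAT2 2.0.4 and the GRCm38 assembly.

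One deposited table was used. It lists 675 genes, all typed as mRNA, with a column per library in FPKM, as the authors' column names give it, and 2 decimals. It also holds 6 columns of the authors' log2 ratio, for OGD against normoxia and OGD+Oba against OGD at each time. No counts or library totals were used here, the lowest FPKM above 0 was 0.01, and the depth is unknown, so no counting interval was computed. The authors' log2 ratio of OGD to normoxia at 6 h was at least 1 in size for all 675 genes, 350 up and 325 down, so the table is a selection on that comparison. Comparisons at 6 h that hold the normoxia or OGD library describe genes chosen on it, and differences there are inflated by that choice. A second consequence is that lists and marker lists could be tested only on members that passed the selection. The sums of FPKM over the table ranged from 14198 (OGD 1 h) to 22631 (OGD+Oba 6 h); they cover the listed genes and are not depths. Gene identifiers were matched to the RefSeq annotation of GRCm38.p6 for 671 genes, which gave positions.

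FPKM values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 580 in all. With 1 library per group, comparisons at 1 time carry no test and are counts of genes with a log2 difference of at least 1 in size. The test over times used limma 3.58.1 in R 4.3.3, with trend, on a model with time and arm as terms, which has 4 residual degrees of freedom and a prior of 21.27. The 3 times stand in as replicates in it, and a change of the OGD effect with time counts as error. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. They measure the spread of single libraries, not of repeated cultures at 1 time.

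A further fit was chosen after seeing the data, because the additive model takes a change of the OGD response with time as error. It has an OGD effect for each time and 1 obacunone effect common to the times, so that OGD and OGD+Oba stand as a pair of deprived libraries. It has 2 residual degrees of freedom, which come from the OGD and OGD+Oba pairs, and a prior of 5.48; the lone normoxia library at each time is assumed to vary like them. The calls at 6 h from it are not independent of the selection of the table.

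Gene lists, 30 in number, and 8 marker lists of other cell types were fixed before the data were examined. Their counts are given over all genes tested and adjusted over the list alone. The 8 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. The median of each list was set against 10000 random lists matched in 10 bins of mean expression. The MIF axis genes were always to be named; they were not analysed here.

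Genes were named by a rule fixed before the data were examined. For OGD against normoxia and OGD+Oba against OGD it took the 6 genes with the highest and the 6 with the lowest mean difference among those called with the same sign at each time, filled where fewer passed. It added the 2 highest and 2 lowest genes at each time, and up to 4 members of each list described, with predicted genes passed over. Other called genes, Icam1, Chac1, Tubb3, Sqstm1 for obacunone, and the genes at least 2-fold apart between OGD+Oba and OGD were named after their values were seen. For obacunone, list members were left out as single genes and given as list medians, a choice also made after their values were seen. Results for some genes that the rule takes are not reported here.

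Whether obacunone moved OGD-changed genes back was asked by the share of genes with opposite signs, with Wilson 95% intervals, which treat genes as independent. Because both differences use the same OGD library, the share was set against simulations without an obacunone effect, and against genes chosen at another time. Sequence sharing was the percent of a gene's 31-base words, over its transcripts, that occur in transcripts of other genes.

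Alternatives were a size of 1.5-fold, a floor of 5 FPKM, no floor, a pseudocount of 0.1, median-ratio scaling, limma without trend or with its robust option, no time term, only the 6 libraries of 2 arms, and leaving out each time. Chosen after the data were seen were the authors' scaling (a shift of each library to match the authors' log2 ratio), leaving out genes with at least 50% of words shared, the share of genes keeping their sign from 3 h to 6 h, the count of called genes beyond all normoxia libraries, and 5 further gene lists. The median-ratio factors were taken over the listed genes alone, all of them selected as changed at 6 h. The premise of that scaling, mostly unchanged genes, is broken there, where the factor was 0.88 for normoxia and 1.15 for OGD. Both fits were tested on simulated data with 200 of 580 genes changed. At a true log2 change of 1 the additive fit called 99.4% and the further fit at 3 h 93.5%; 3.3% and 3.2% of calls were false. The simulated effect was the same at each time for the additive fit and lay at 3 h only for the further fit. The simulated noise was that of the further fit, without a change of the OGD effect with time. The share called by the additive fit therefore does not carry over to these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.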

Results

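The data are RNA-seq profiles of mouse brain microvascular endothelial cells, the cells that line brain capillaries and form the blood-brain barrier. They were kept in normoxia, without oxygen, glucose and serum (oxygen-glucose deprivation, OGD, a culture model of ischemia), or in OGD with 3 µM obacunone (OGD+Oba), for 1, 3 or 6 h. Obacunone is a limonoid from citrus fruit. Each of the 9 groups held 1 library, so no difference between 2 libraries has a replicate check. The deposited table listed 675 genes in fragments per kilobase of transcript, scaled to the fragments mapped (FPKM), and 580 of them had a mean of at least 1 FPKM and were tested. Every listed gene differed at least 2-fold between OGD and normoxia at 6 h in the authors' deposited table, 350 higher and 325 lower. The 6 h OGD comparison therefore describes a list chosen on it, while the 1 h and 3 h libraries took no part in that choice. Sequencing depth is unknown, and no counting interval can be given.

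OGD against normoxia asks how the cells answered the joint withdrawal of oxygen, glucose and serum. Genes of the hypoxia response were far higher in the OGD libraries at 3 h and 6 h, and those of glucose sensing, matrix signalling and fibrinolysis were lower. Vegfa, the main endothelial growth factor (NCBI gene 22339, chromosome 17, 46016993 to 46032377, GRCm38.p6), stood at 18.5, 86.9 and 214 FPKM under OGD at 1, 3 and 6 h, against 19.1, 7.01 and 7.74 in normoxia. Txnip, an arrestin that limits glucose uptake (gene 56338, chromosome 3, 96557957 to 96561857), stood at 289, 43.8 and 43.7 FPKM under OGD against 676, 486 and 492.

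Over the 3 times together, 18 genes rose and 6 fell under OGD at an adjusted p of 0.05. Folds from this fit are log2 values ± SE over 3 libraries per arm. Ankrd37, a hypoxia-induced ankyrin repeat gene (gene 654824, chromosome 8, 45996908 to 46000414), rose most, by 3.05 ± 0.56 (adjusted p = 0.00104). Ppp1r3c, which targets a phosphatase to glycogen, rose by 2.91 ± 0.47, and Ppp1r3b, of the same kind, by 1.36 ± 0.39. Vegfa rose by 2.68 ± 0.62, the ephrin ligand Efna1 by 2.53 ± 0.53, Ndrg1 by 2.25 ± 0.57 and Smtnl2 by 2.17 ± 0.45. The oxygen sensor Egln3 rose by 1.83 ± 0.52, the clock repressor Nr1d1 by 1.65 ± 0.47 and the transcription factors Prdm1 and Sox9 by 2.07 ± 0.50 and 1.67 ± 0.48. Depp1, Kctd11 and Dipk2a rose by 2.42, 1.57 and 1.47. Those 3, Ppp1r3b, Prdm1 and Sox9 were named after their values were seen. The histone gene H3c10 was called higher, at 2.18, 2.22 and 5.23 FPKM under OGD; it was listed at 0 in all normoxia libraries, and 94.2% of its 31-base words also lie in other genes.

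Among the genes that fell, the predicted gene Gm14819 changed most, by -5.81 ± 0.63, and Txnip next, by -2.71 ± 0.50 (adjusted p = 0.00104). Mmp10, a secreted matrix protease, fell by 1.56 ± 0.31 on the log2 scale and Ccn2, a matricellular protein and YAP target (gene 14219, chromosome 10, 24595442 to 24598683), by 1.59 ± 0.46. LOC115490151 and Gm8764 also fell, and Gm21293, Gm21451 and Gm10147 were among those that rose. These 5 and Gm14819 were named after their values were seen; LOC115490151 had no transcript match, and the others share 98.5% to 100% of their 31-base words with other genes. Plk3, Plat and Sgk1 missed this test, with log2 differences of -1.03 ± 0.41, -1.52 ± 0.47 and -1.37 ± 0.46. The fit takes a change of the OGD response with time as error, and a rise to 6 h is in part fixed by the choice of genes. The fit called 437 genes without the 1 h libraries, 6 without 3 h and 3 without 6 h. With median-ratio scaling it called 6, 3 in each direction.

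By the rule of at least 2-fold, 4 genes were higher and 18 lower under OGD at 1 h, 86 and 49 at 3 h, and 224 and 172 at 6 h. At 3 h, 535 of 580 genes (92.2%) had the sign of their 6 h difference, and so did 134 of the 135 that were at least 2-fold apart. The exception was the chemokine Ccl2, with log2 differences of -1.27 at 3 h and 0.93 at 6 h. At 1 h only 271 genes (46.7%) had that sign, near the 50% that unrelated signs give. Across genes, which are not independent replicates, the log2 differences at 3 h and 6 h correlated with r = 0.87, and those at 1 h and 6 h with r = -0.05; each pair uses separate libraries. Median-ratio scaling turned the 6 h split to 150 higher and 246 lower, and the authors' scaling gave 244 and 147. The median-ratio factors come from the listed genes alone, all chosen as changed at 6 h, so they cannot settle that split. The median over all genes at 6 h was 0.78 and 0.50 after median-ratio scaling. Without genes that share sequence, 0 were higher and 14 lower at 1 h.

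A fit added after these values were seen treated OGD and OGD+Oba at each time as a pair of deprived libraries. In limma it called 0 genes higher and 22 lower at 1 h (63 at an unadjusted p of 0.05), 181 and 144 at 3 h, and 307 and 259 at 6 h. At 1 h the total was 34 without the 3 h libraries and 36 without the 6 h libraries. Its adjusted p values stand behind the words rose and fell at single times below, with log2 values ± SE. The error comes from the OGD and OGD+Oba pairs alone, the lone normoxia library is assumed to vary like them, and a fault in it cannot be separated from the effect of OGD. Both deprived libraries lay beyond all 3 normoxia libraries, a check chosen after the data were seen, for 11 of the 22 genes called at 1 h, 286 of 325 at 3 h and 517 of 566 at 6 h.

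**Figure D1:**
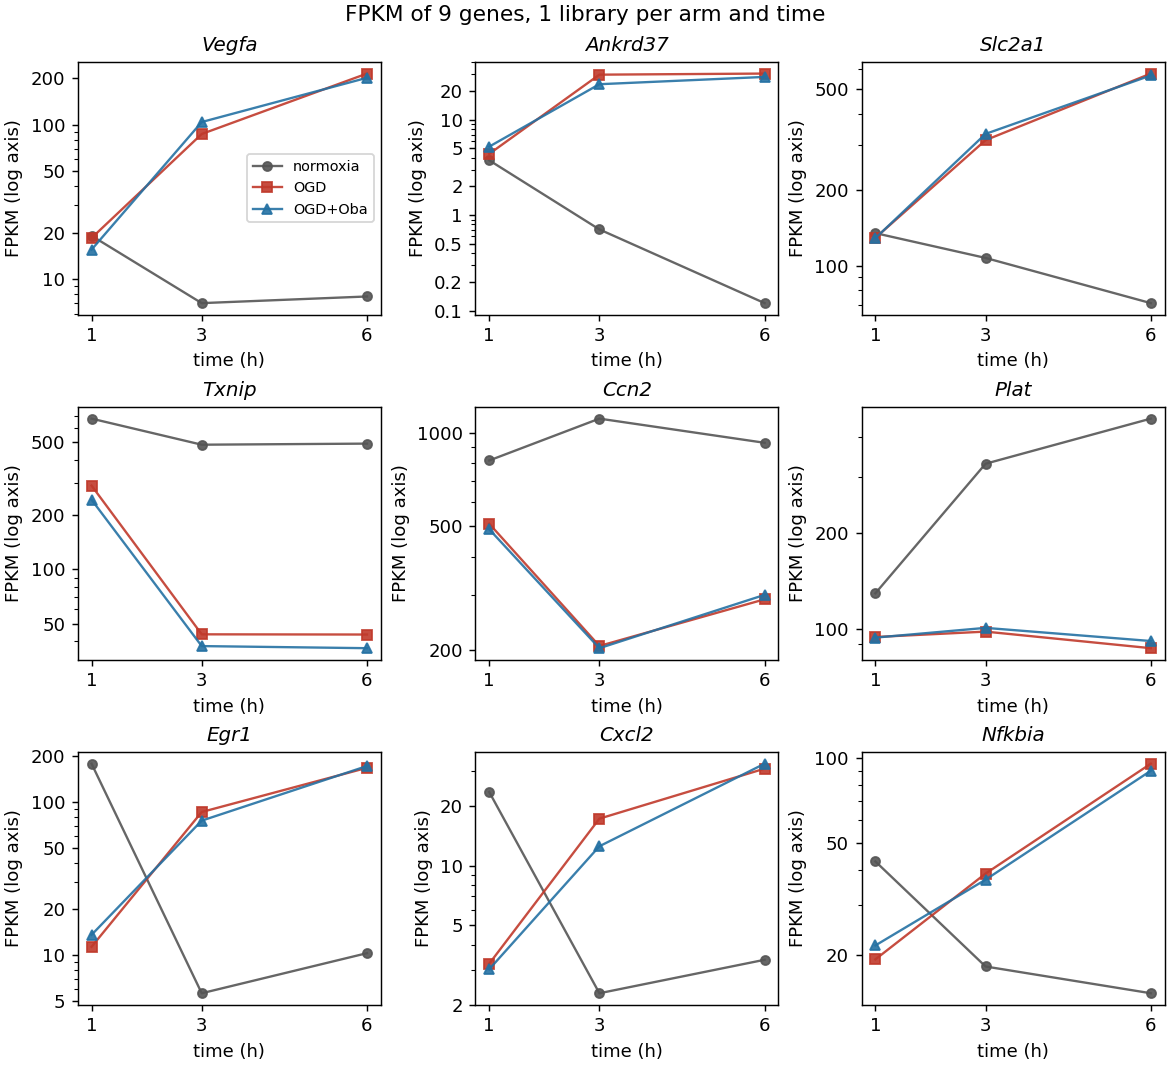
FPKM of 9 genes on a log axis against hours of incubation (1, 3 and 6), with 1 point per library and lines for normoxia, OGD and OGD+Oba. The OGD and OGD+Oba lines lie close together. Vegfa reaches 214 FPKM and Txnip falls to 43.7 FPKM under OGD at 6 h, and Egr1 lies at 179 FPKM in normoxia at 1 h against 5.65 at 3 h.

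Of the 16 tested targets of HIF-1, the oxygen-sensitive transcription factor, 15 rose at 3 h (16 when adjusted over the list alone) and 16 at 6 h. Their median log2 difference was 0.00, 1.56 and 2.69 at 1, 3 and 6 h, at percentile 99.8 of random lists at 3 h. Over the 3 times, 4 rose (13 adjusted over the list alone). At 3 h Ankrd37 rose by 4.04 ± 0.22, Vegfa by 3.60 ± 0.17, Ndrg1 by 2.31 ± 0.15 and Egln3 by 2.07 ± 0.10. In normoxia the same list drifted down, with a median of -0.89 at 6 h against 1 h and 14 of 16 lower. Of 5 glycolytic enzymes, 2 rose at 3 h and 5 at 6 h, also when adjusted over the list alone, with medians of 0.38 and 0.92, at percentiles 66.5 and 47.5 of random lists, so not apart from them. Hexokinase Hk2 rose by 2.18 ± 0.12 at 3 h and phosphofructokinase Pfkl by 0.61 ± 0.10; Pfkp and Aldoc, at 0.32 and 0.30, were called only at 6 h. The glucose transporter Slc2a1 of the barrier rose by 1.57 ± 0.09 at 3 h and 2.98 ± 0.09 at 6 h, and the transferrin receptor Tfrc rose at 6 h, by 0.96 ± 0.11.

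Immediate early genes, which respond to growth factors and stress, were lower under OGD at 1 h and higher from 3 h. Of 10 tested, 8 fell at 1 h (9 adjusted over the list alone), 8 rose at 3 h and 10 at 6 h, with medians of -1.42, 1.32 and 1.91. Egr1 (gene 13653, chromosome 18, 34861207 to 34864956) fell by 3.76 ± 0.15 on the log2 scale at 1 h and rose by 3.61 ± 0.15 at 3 h. Junb fell by 1.26 ± 0.13, Atf3 by 1.37 ± 0.14 and Ier3 by 0.86 ± 0.13 at 1 h, and at 3 h they rose by 1.65, 1.66 and 2.82. Of 9 NF-kB and inflammatory genes, 4 fell at 1 h (6 adjusted over the list alone), 5 rose and 2 fell at 3 h (5 and 3 alone), and 8 rose and 1 fell at 6 h. The neutrophil chemokines Cxcl1 and Cxcl2 fell by 2.98 ± 0.18 and 2.50 ± 0.21 at 1 h, and rose by 1.28 and 2.33 at 3 h. The inhibitors Nfkbia and Tnfaip3 fell by 1.04 ± 0.13 and 1.35 ± 0.20 at 1 h, and rose by 1.02 and 0.97 at 3 h. Csf2 rose by 1.05 ± 0.25 at 3 h, Ccl2 fell at 3 h and rose at 6 h, and the adhesion molecule Icam1 fell at both.

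These genes stood high in normoxia at 1 h. Egr1 was at 179, 5.65 and 10.3 FPKM in normoxia at 1, 3 and 6 h and at 11.4 under OGD at 1 h. All 10 immediate early genes were lower in normoxia at 3 h than at 1 h, by a median of -1.91, and the inflammatory list was lower by -0.69. At 1 h the deprived libraries of Egr1, Atf3, Ier3, Cxcl2, Nfkbia, Cited2, Hes1 and Sgk1 lay within the range of the normoxia libraries, and those of Cxcl1 and Tnfaip3 below it. At 3 h those of Egr1, Atf3, Cxcl1, Cxcl2, Nfkbia and Ccl2 lay within that range, and at 6 h still those of Egr1, Fos, Fosb, Cxcl1, Atf3 and Zfp36. Nor did both deprived libraries of Ccl2, Tfrc and Chac1 lie beyond that range at 6 h. With median-ratio scaling the 1 h fit called 10 genes, and without shared-sequence genes 1 higher and 34 lower.

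Most tested genes of the ATF4 and growth factor withdrawal lists rose from 3 h. Of 6 ATF4 targets, genes of the amino acid and endoplasmic reticulum stress response, 5 rose at 3 h, also adjusted over the list alone, with a median of 1.19. The mTOR inhibitor Ddit4 rose by 2.53 ± 0.10, Ddit3 by 1.67 ± 0.14, Ppp1r15a by 1.39 ± 0.17 and Vldlr by 0.83 ± 0.19; Chac1 was not called at 3 h and fell at 6 h. Of 7 genes induced by growth factor withdrawal and FOXO factors, 5 rose at 3 h and 7 at 6 h, also over the list alone, with medians of 1.25 and 1.82. Cited2 fell by 0.56 ± 0.10 at 1 h and rose by 2.98 ± 0.10 at 3 h, and the cell cycle brakes Ccng2 and Cdkn1b rose by 1.67 ± 0.11 and 1.66 ± 0.12, and Foxo3 by 1.34 ± 0.19. Heme oxygenase Hmox1 rose by 1.3 ± 0.11 at 3 h, the chaperone Dnajb1 by 0.61 ± 0.13, Irf1 by 0.96 ± 0.14, and the dioxin-responsive Cyp1a1 and Tiparp by 2.08 ± 0.13 and 1.57 ± 0.24. The Notch target Hes1 fell by 0.93 ± 0.16 at 1 h and rose by 1.98 ± 0.16 at 3 h. The autophagy gene Gabarapl1 rose by 0.46 ± 0.10 at 3 h, while its companion Sqstm1 (0.19 ± 0.07, adjusted p = 0.0575; called when adjusted over the list alone) and the death gene Bcl2l11 (0.61 ± 0.28) passed over all genes only at 6 h. Cdkn1a was higher by 0.24 ± 0.09 at 3 h, less than the median difference of 0.28 to 0.48 between normoxia libraries; median-ratio scaling ended its call and that of Gabarapl1. The 3 h values of Ppp1r15a and Dnajb1 lay within the range of the normoxia libraries, as did 1 of those of Hes1.

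Genes of glucose sensing, cell tension and fibrinolysis fell, and so did the 2 tested genes of the junction list. Txnip fell by 1.23 ± 0.09 at 1 h and 3.43 ± 0.09 at 3 h on the log2 scale, and its relative Arrdc4 by 0.75 ± 0.19 at 3 h. All 3 tested YAP targets fell at 3 h, also over the list alone, with a median of -1.85: Ccn2 by 2.42 ± 0.08, Amotl2 by 1.81 ± 0.15 and Ankrd1 by 0.94 ± 0.09. The matrix protease Mmp10 and the plasminogen activator Plat fell at 3 h, by 1.82 ± 0.22 and 1.73 ± 0.09, also when adjusted over the list alone; for Mmp10 1 of the 2 deprived libraries lay within the range of the normoxia libraries. Plat (gene 18791, chromosome 8, 22757722 to 22782848) was at 98.3 FPKM under OGD at 3 h against 329 in normoxia. The junction genes Cldn12 and Marveld2, from a list of 16 of which 2 were tested, fell by 0.96 ± 0.19 and 0.90 ± 0.22 at 3 h. Of 2 claudins outside that list, named after their values were seen, Cldn4 was higher and Cldn9 lower. At 3 h Cldn4 was at 271 FPKM under OGD against 97.6 in normoxia, and Cldn9 at 5.58 against 8.49. The kinases Plk3 and Sgk1 fell at each time, by 0.91 ± 0.15 and 1.83 ± 0.08 at 3 h. The mitotic kinase Aurka fell by 0.57 ± 0.11 and the neuronal marker Tubb3 by 1.33 ± 0.20. The reference gene Gusb was lower, with a log2 difference of -0.41 ± 0.12 whose call median-ratio scaling ended.

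As sets over the 3 times, HIF-1 targets (adjusted p = 4.91e-07), FOXO genes (0.0156) and YAP targets (0.0261) passed camera with its preset correlation, among 8 lists tested. None passed with an estimated correlation, where the lowest adjusted p was 0.528. The members tested, 16 of 24 HIF-1, 7 of 15 FOXO and 3 of 10 YAP genes, are those that passed the selection at 6 h. The 6 h libraries are in the fit, so these p values depend on that selection and do not cover the whole lists. The matrix protease list missed camera (adjusted p = 0.109), and its genes fell on balance by fry, a test of direction within the list (adjusted p = 0.00285). It was the only list to pass fry. HIF-1 targets (fry, adjusted p = 0.171), FOXO genes (0.171) and YAP targets (0.0765) missed it. The other lists had adjusted camera p of 0.119 to 0.435. The MIF axis, endoplasmic reticulum chaperones, actin and SRF targets, oxidative phosphorylation, mitochondrially encoded genes, basement membrane and cytosolic ribosomal proteins were not analysed here, nor were 7 of the 8 lists of other cell types.

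**Figure D2:**
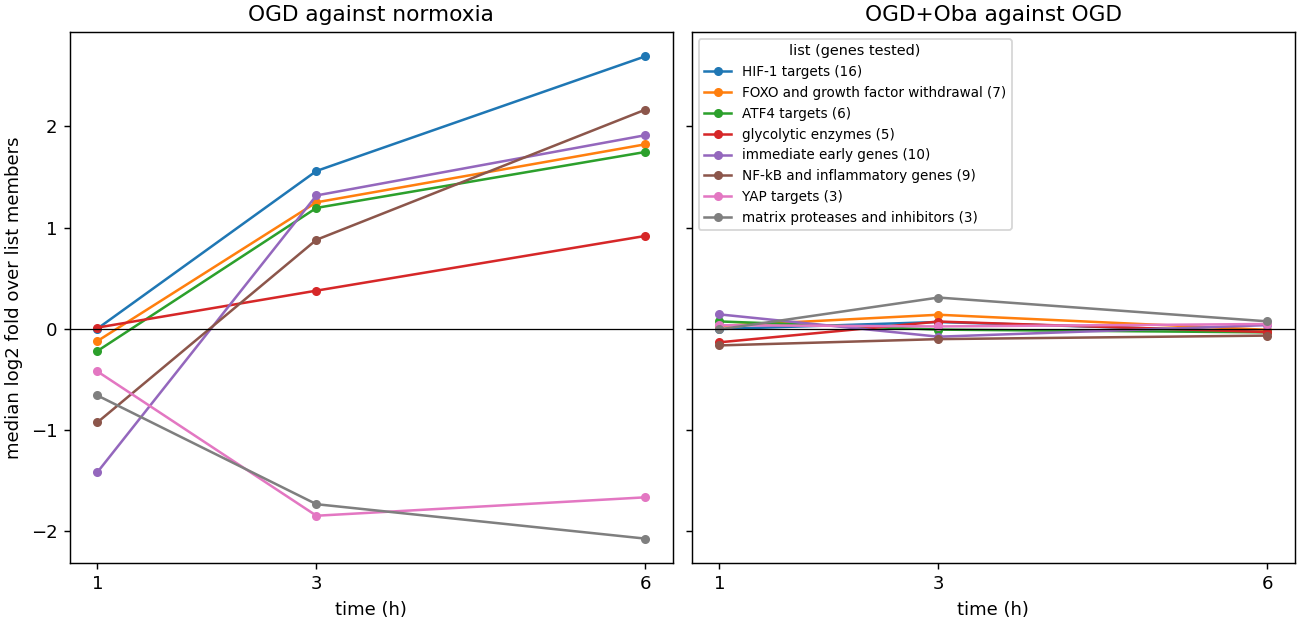
Median log2 difference of 8 gene lists at 1, 3 and 6 h, with OGD against normoxia on the left and OGD+Oba against OGD on the right, each median over the tested members of 1 pair of libraries. HIF-1 targets reach 2.69 under OGD at 6 h, and the obacunone medians all lie between -0.16 and 0.31.

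Normoxia libraries give the scale of differences without deprivation. Between normoxia at 3 h and 1 h, 16 genes were at least 2-fold higher and 31 lower. Between 6 h and 3 h the counts were 5 and 13 (12 and 11 after median-ratio scaling), and between 6 h and 1 h 21 and 64 (43 and 42). Plat stood at 130, 329 and 455 FPKM at 1, 3 and 6 h, and Ankrd37 at 3.76, 0.71 and 0.12. Time in culture and library differences cannot be separated in these pairs.

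OGD+Oba against OGD asks whether obacunone altered the response to deprivation. Only genes at least 2-fold apart between OGD and normoxia at 6 h are listed, so genes that obacunone changed and OGD did not would be absent. Among the tested genes, none outside families of near-identical copies passed the test. The treated and untreated OGD libraries differed by a smaller median size than the normoxia pairs, which also differ in time. The median size of the log2 difference was 0.17, 0.14 and 0.11 at 1, 3 and 6 h, against 0.12, 0.63 and 1.14 for OGD against normoxia and 0.28 to 0.48 between normoxia libraries. The normoxia and OGD libraries at 6 h took part in the choice of genes. Normoxia at 3 h against 1 h, which took no part in it, had a median size of 0.32. The SD of the log2 difference was 0.47 for obacunone at 1 h, above the 0.46 of normoxia at 6 h against 3 h; without genes that share sequence the order turned, at 0.27 and 0.44. Txnip, the glucose-sensing arrestin that fell under OGD, was at 289, 43.8 and 43.7 FPKM under OGD and at 242, 37.7 and 36.7 with obacunone. Mmp10, the matrix protease, was at 0.54, 1.18 and 0.78 FPKM under OGD and at 1.04, 1.91 and 1.76 with obacunone.

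Over the 3 times, 4 genes rose and 2 fell with obacunone (limma, 10 at an unadjusted p of 0.05). Gm10487 rose by 2.80 ± 0.50 on the log2 scale (adjusted p = 0.00478), from 13.1, 2.68 and 1.5 FPKM under OGD to 52.6, 22.3 and 33.8. It lies on chromosome X, 30820542 to 30843469, and 100% of its 31-base words occur in other genes. The other 5 were Gm14819, Gm21304 and Gm8764, higher, and Gm21293 and Gm21451, lower; each was listed at 0 in at least 1 library of an arm and shared 98.5% to 100% of its words. Gm8764, for one, was listed at 0 in all OGD libraries and at 5.14, 5.39 and 0 FPKM with obacunone. In the added fit Gm10487 alone was called (22 genes at an unadjusted p of 0.05); the count was 12 without the 1 h libraries, 6 without 3 h and 13 without 6 h. Leaving out 36 genes that share at least 50% of their words, the additive limma test called 0 (0 at an unadjusted p of 0.05). The added fit then called 1, Gm20594, higher by 0.43 ± 0.09 on the log2 scale and named after its values were seen. The additive test called 2 genes without the 6 h libraries. Its error holds the change of the OGD effect with time, so it can miss an obacunone effect. A count of 0 from it does not show that there was none. With only the 6 libraries of the 2 arms it called 1 of 580 genes (limma, 21 at an unadjusted p of 0.05).

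Among named single-copy genes, the largest steady differences missed the test. Mmp10, the protease that OGD lowered, was higher with obacunone by 0.41, 0.42 and 0.63 at 1, 3 and 6 h. Its FPKM lie near 1, where the pseudocount shrinks a difference: the authors' log2 ratios were 1.07, 0.68 and 1.17, and with a pseudocount of 0.1 the difference over the 3 times was 0.85 against 0.49, again not called. Txnip was lower, by -0.26, -0.21 and -0.24. Areg, a growth factor of the EGF family, was higher by 0.19, 0.49 and 0.29. The mitophagy receptor Bnip3 and Oser1 were higher by 0.09 to 0.23. Lower at each time were Cxcl5 (-0.20, -0.10, -0.22), cyclin Ccnd1 (-0.13, -0.08, -0.12), Nr1d1 (-0.09, -0.12, -0.08), Atxn7l2 (-0.25, -0.17, -0.11) and Pnma3 (-0.47, -0.21, -0.09). The authors' scaling raises every 1 h difference by 0.14, more than the size of those of Ccnd1 and Nr1d1. Fos differed by 0.87, -0.19 and 0.09, the demethylating enzyme Tet2 lower by -0.98 at 1 h and higher by 0.81 at 3 h, and Ccl2 lower by -0.66, -0.07 and -0.62, which the added fit called without the 3 h libraries only. Histone genes H1f5 (-0.65, -0.75, 0.18) and H1f4 went both ways, and Hist1h2ao was listed at 0, 1.04 and 5.7 FPKM under OGD and at 1.94, 2.18 and 7.2 with obacunone. H3c14 (3.51, 0 and 3.12 FPKM under OGD) and H2ac19 (3.5, 1.63 and 0) were listed at 0 in all OGD+Oba libraries; these 3 share 93.8% to 100% of their words. The zinc finger gene Zfp967, all of whose words are shared, was higher by 1.05 at 3 h.

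Adjusted over the list alone, 3 genes passed in the added fit among 23 lists so examined: Mmp10 rose by 0.49 ± 0.14, the autophagy receptor Sqstm1 by 0.14 ± 0.05, and Txnip fell by 0.24 ± 0.06 on the log2 scale. Over all genes tested their adjusted p were 0.474, 0.819 and 0.446. In the additive fit 0 of these genes passed when adjusted over the list alone. Sqstm1 was named after its values were seen. No list passed camera (lowest adjusted p = 0.767, and 0.984 with an estimated correlation). Medians of the inflammatory list were -0.16, -0.10 and -0.07 and those of immediate early genes 0.14, -0.08 and 0.04 at 1, 3 and 6 h, with these signs under each scaling tried. HIF-1 targets had medians of 0.07 at 3 h and -0.03 at 6 h, and glycolytic enzymes 0.07 and -0.03; median-ratio scaling turned these to -0.07, 0.03, -0.06 and 0.03.

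By the 2-fold rule, 5 genes were higher and 12 lower with obacunone at 1 h (7 and 8 with median-ratio or the authors' scaling), 3 and 4 at 3 h, and 3 and 2 at 6 h. Without genes that share sequence the counts were 0 and 6, 0 and 0, and 0 and 0. The 6 at 1 h were Ogt, Far2, Ptbp2, Rhof, H60b and 1700024J04Rik, named after their values were seen. Ogt, the enzyme that adds sugar to nuclear proteins, was at 23.0 FPKM with obacunone against 50.4 under OGD at 1 h and at 40.0 against 23.4 at 3 h.

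**Figure D3:**
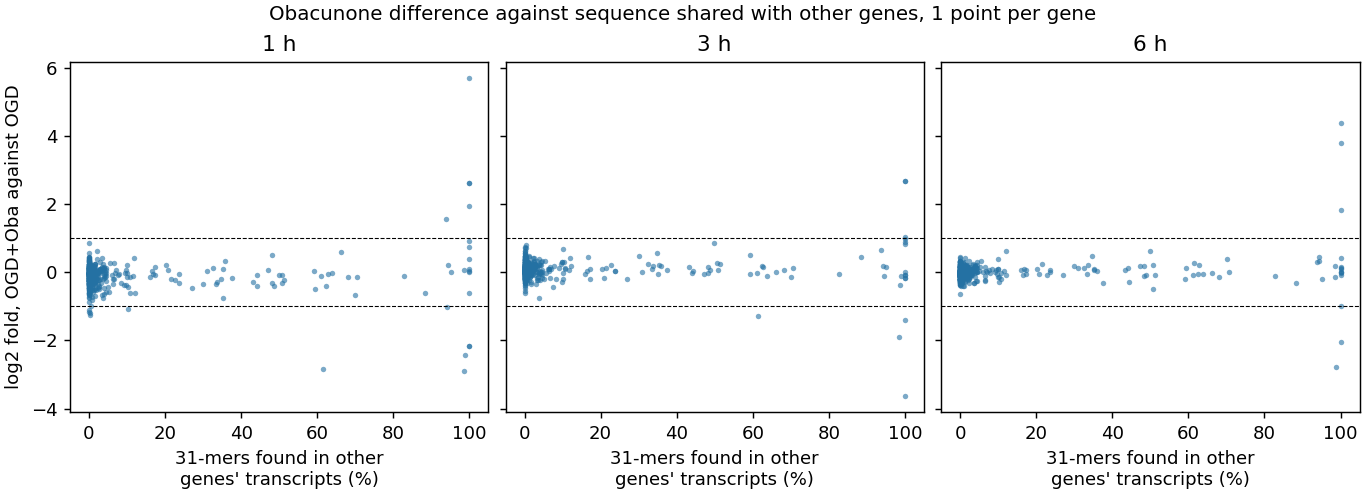
Log2 difference between OGD+Oba and OGD for each gene at 1, 3 and 6 h against the percent of its 31-base words found in other genes, with dashed lines at 2-fold. Of 19 genes beyond the lines at any time, 13 share at least 50% of their words and 5 share less; 1 had no transcript match and is not drawn.

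Whether obacunone moved OGD-changed genes back was asked by sign. Of genes at least 2-fold apart between OGD and normoxia, 15 of 22 (68.2%, Wilson 95% interval 47.3% to 83.6%) had the opposite sign for obacunone at 1 h, 76 of 135 (56.3%, 47.9% to 64.4%) at 3 h, and 196 of 396 (49.5%, 44.6% to 54.4%) at 6 h. With the shared OGD library, simulations gave 58.2%, 57.9% and 56.1% when the observed OGD differences were taken as true and obacunone had no effect. They gave 82.7%, 83.6% and 79.0% with no effect at all. The observed differences already hold the noise of the OGD library, so the first shares are approximate. With genes chosen at another time, and so no shared library, 39.3% of those chosen at 3 h were opposite at 1 h and 38.5% at 6 h, and 41.9% of those chosen at 6 h were opposite at 3 h and 49.7% at 1 h. Of those chosen at 1 h, 54.5% were opposite at 3 h and 50% at 6 h. The covariance of the differences was -0.146, -0.0606 and -0.0652, against -0.0319, -0.0319 and -0.0325 simulated from the shared library. Without shared-sequence genes it was -0.0271, -0.0361 and 0.00638 against -0.0260, and 7 of 14 genes (50%) were opposite at 1 h. Each control is 1 library and cannot be split, so the part that the shared library adds was not measured.

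OGD+Oba against normoxia asks what deprivation did in the presence of obacunone. The hypoxia genes were again higher from 3 h, and the glucose-sensing arrestin was lower at each time. Vegfa, the growth factor, was at 15.5, 104 and 201 FPKM with OGD+Oba at 1, 3 and 6 h, against 19.1, 7.01 and 7.74 in normoxia, and Ankrd37 at 5.23, 23.6 and 28.1 against 3.76, 0.71 and 0.12. Txnip was at 242, 37.7 and 36.7 FPKM against 676, 486 and 492. Over the 3 times 19 genes rose and 8 fell. HIF-1 targets (camera, adjusted p = 3.32e-07), FOXO genes (0.0189) and YAP targets (0.0347) passed, with an adjusted p of 0.501 for each with an estimated correlation. By fry these 3 lists missed (adjusted p = 0.197, 0.197 and 0.0778), and the matrix protease list alone passed (0.00758). Here too the members tested had passed the selection at 6 h, which used the same normoxia library. The count was 433 without the 1 h libraries, 2 without 3 h and 0 without 6 h (31 at an unadjusted p of 0.05). It was 74 with limma's robust option, 57 without shared-sequence genes, and 0 with median-ratio scaling (172 at an unadjusted p of 0.05).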

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

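The tests of single explanations below were chosen only after the result was seen, except that of family sums, though the count of sums that outmoved their members and the present form of the normoxia and admixture tests came after a first form, and the tests of a change in the OGD effect with time come from the fit added after the data were seen.

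The effect of OGD differed between times in the fit with an OGD effect per time. Between 3 h and 1 h it differed for 215 genes, 153 with a higher effect at 3 h and 62 lower. Between 6 h and 1 h it differed for 492 genes, 282 higher and 210 lower, and between 6 h and 3 h for 170, 114 higher and 56 lower. Median-ratio scaling turned these splits to 132 and 95, 223 and 245, and 39 and 102. Each comparison with 6 h uses genes selected at 6 h. The error of these tests comes from the OGD and OGD+Oba pairs alone, so any difference between the lone normoxia libraries counts as a change of effect. The deprived libraries changed more than normoxia between the times in 131 of the 215 genes, 333 of the 492 and 79 of the 170.

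The genes called lower at 1 h and higher at 6 h were 16. Their OGD effect at 6 h minus that at 1 h, in log2, was 7.67 for Egr1, 5.56 for Fos, 5.48 for Cxcl2, 5.28 for Cxcl1, 4.18 for Cited2, 4.09 for Atf3, 3.70 for Junb and 3.69 for Ier3. It was 3.62 for Nfkbia, 3.61 for Tnfaip3, 3.21 for Dusp5, 3.19 for Fosb, 3.12 for Zfp36, 2.60 for Klf10, 2.46 for Dusp1 and 2.39 for Hes1. All but Fosb and Zfp36 were also called higher at 3 h. At 6 h the deprived libraries of Egr1, Fos, Fosb, Cxcl1, Atf3 and Zfp36 lay within the range of the normoxia libraries, where normoxia at 1 h is the highest.

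The first pattern is the set of 22 genes called lower under OGD at 1 h. A difference in scaling of the OGD and normoxia libraries is argued against for the set as a whole, since the median over all 580 genes was -0.0081 at 1 h, and -1.23 over these genes. In the fit, which also holds OGD+Oba, the median over all genes was -0.052. Single calls do depend on scaling: the fit called 10 genes with median-ratio scaling and 18 with the authors' scaling. A raised normoxia 1 h library, as after a change of medium, is a candidate explanation: over the 10 immediate early genes of the fixed list, it stood above the mean of later normoxia by a median of 1.80, and OGD at 1 h by 0.47. Loss of a response to serum, glucose or oxygen stays open, because 0 groups had only 1 of these withheld. Over all 22 genes, normoxia at 1 h stood above later normoxia for 20. For Ccn2 and Plat it stood below, by -0.32 and -1.57, so no raised level is seen for them. Both deprived libraries lay below all 3 normoxia libraries for 11 of the 22. With 1 normoxia library at 1 h the explanations cannot be told apart further.

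The second pattern is the set of 19 genes at least 2-fold apart between OGD+Oba and OGD at any time. Their median share of 31-base words found in other genes was 98.7%, against 0.196% in the rest, so assignment of reads between near-identical copies may account for most of them. Whether reads only moved between listed copies stays open: over 3 families the median size of the difference of the summed FPKM was 0.326 of that of the members, within the limit set beforehand, but 2 of 9 sums moved more than their median member, and that of the Gm21293 family was higher with obacunone at each time, by 0.60, 0.85 and 0.65. An effect of obacunone common to the times is argued against for most of the set, since 2 of 19 genes had the same sign and a size of at least 0.5 at each time; what set apart the 5 genes that share less than 50% of their words was not tested.

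The third pattern concerns 10 genes of epithelial barriers, a list written after the values were seen. Of them 4 stood at high FPKM, Cldn4 at 60.9 to 308, Elf3 at 40.3 to 185, Krt6a at 26.0 to 71.4 and Epn3 at 25.5 to 64.8. Rab17 stood at 9.58 to 27.4, Marveld2 at 5.80 to 16.2, Cldn9 at 4.07 to 13.8 and Gcnt3 at 4.66 to 13.4. Il22ra1 stood at 0.26 to 2.05 and Prss8 at 0.05 to 0.96, while the endothelial gene Flt1 reached at most 0.68 FPKM. Admixture of epithelial cells in some libraries stays open: beyond the OGD response the largest difference had a median of 0.66 over 10 genes and reached 1.17, and from normoxia at 1 h to 6 h 6 of the genes were higher and 4 lower. Expression of such genes by the culture itself could not be decided, since Flt1 was the only 1 of 18 endothelial identity genes analysed here. Because the 10 genes were picked after their values were seen, their high FPKM does not show what the culture is. The 4 genes of the epithelial marker list fixed beforehand were not analysed here. Of the 10 epithelial genes, Marveld2 is also in the fixed junction list.

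For the fits over the 3 times, the 6 libraries of 2 arms make 10 splits, too few for a share under 0.05. OGD against normoxia called 24 genes and the highest other split 89, with 2 of 10 splits at least as large. OGD+Oba against normoxia called 27 and the highest other 88, with 2 of 10. In both, the higher split exchanges the labels of the 1 h libraries. Why that exchange called more genes was not tested. OGD+Oba against OGD called 6 and the highest other split 1, with 1 of 10 as large.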

How the results depend on the processing

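The fit with an OGD effect per time, the authors' scaling and leaving out shared-sequence genes were chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible by replicate number, because the labels give none; the time term matches libraries by time. Depth is unknown, so it cannot be said which low values or differences counting noise limits. A size of 1.5-fold gave 46 genes for OGD at 1 h, 312 at 3 h, 50, 22 and 9 for OGD+Oba against OGD at 1, 3 and 6 h, and 136, 89 and 229 for normoxia 3 h against 1 h, 6 h against 3 h and 6 h against 1 h, as a lower bar must. A floor of 5 FPKM gave 6, 2 and 2 for OGD+Oba against OGD, and a pseudocount of 0.1 gave 32, 15 and 8, and 40 for normoxia 6 h against 3 h. Without shared-sequence genes, OGD at 1 h had 14, and OGD+Oba against OGD 6, 0 and 0. Over the 3 times, OGD against normoxia (24 genes) ranged from 3 to 437 when a time was left out, and was 44 with the robust option, 6 with median-ratio scaling, 0 with no time term (135 at an unadjusted p of 0.05) and 14 with the smaller pseudocount. All 24 were among the calls without 1 h, 6 among those without 3 h, 3 without 6 h, and 6 with median-ratio scaling. OGD+Oba against OGD (6 genes) ranged from 2 to 7 with a time left out; it was 3 with the robust option, 2 at the higher floor and 1 with only the 6 libraries of the 2 arms. It was 0 without the trend (10 unadjusted), with median-ratio scaling (9), with no time term (8), with the smaller pseudocount (10) and without shared-sequence genes (0). OGD+Oba against normoxia (27 genes) ranged from 0 to 433 with a time left out, and was 74 with the robust option, 17 without the trend, 14 with the smaller pseudocount and 57 without shared-sequence genes. It was 0 with median-ratio scaling (172 unadjusted) and with no time term (161). In the fit per time, OGD at 1 h (22 genes) ranged from 34 to 36 with a later time left out, and was 10 with median-ratio scaling and 35 without shared-sequence genes; OGD at 6 h was 370 at the higher floor, where fewer genes are tested. Its obacunone effect (1 gene) ranged from 6 to 13 with a time left out, and was 0 without the trend (18 unadjusted) and with median-ratio scaling (16). With genes chosen at another time, 39.3% were opposite at 1 h (chosen at 3 h; 49.7% chosen at 6 h), 41.9% at 3 h (chosen at 6 h; 54.5% chosen at 1 h) and 38.5% at 6 h (chosen at 3 h; 50% chosen at 1 h). No list passed camera with an estimated correlation for OGD, 0 against 3. Of list medians, median-ratio scaling moved HIF-1 targets to 0.15 and glycolytic enzymes to -0.0092 for obacunone at 1 h, immediate early genes to 0.10 at 6 h, and YAP targets to 0.19 at 1 h, -0.11 at 3 h and, for OGD at 6 h, -2.04. The authors' scaling moved glycolytic enzymes to -0.0206 and YAP targets to 0.17 for obacunone at 1 h. Single genes that changed sign over the 3 times were not called in the setting that turned them. For OGD with a time left out, Egr1 ranged from -0.0729 to 3.81, Cxcl1 from -0.78 (without 6 h; -0.41 without 3 h) to 1.79, Cxcl2 from -0.0322 to 2.67, Nfkbia from -0.0302 to 1.84, Tnfaip3 from -0.18 to 1.56 and Cdkn1a from -0.0266 to 0.69, each lowest without 6 h and highest without 1 h. For obacunone Fos ranged from -0.0465 (without 1 h) to 0.48 (without 3 h), and Tet2 from -0.60 (without 3 h) to 0.30 (without 1 h). Of the other values of single genes over the 3 times, 810 planned and 167 added kept direction and side of the threshold, 57 and 3 passed it and 158 and 6 no longer did, with the same direction; in the fit per time 1126 kept both and 41 no longer passed. For obacunone, members of lists were not followed as single genes, a choice made after their values, near 0, were seen to change sign between settings. Beyond settings that test fewer genes or lower a bar, the cause was not tested.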

Other observations

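The gene lists in this part were written after the values were seen, as were the tests on them.

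By the cellular component terms of the table, 341 of 645 annotated genes were higher under OGD at 6 h. By term, 47 of 60 mitochondrion genes were higher at 6 h, and 42 of the 53 tested were higher at 3 h, with a median log2 difference of 0.43. Among chromatin genes 16 of 18 were higher at 6 h and among integral membrane genes 60 of 147. These 3 of 51 terms examined were picked after their values were seen.

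Clock and clock output genes, 8 in number, had a median log2 difference of 1.45 under OGD at 3 h and 1.36 at 6 h. At 3 h Nr1d1 was higher by 2.70, Bhlhe40 by 2.22, Nfil3 by 1.61, Ciart by 1.57, Dbp by 1.34 and Rora by 0.53, while Cry2 and Arntl2 were lower, at -0.12 and -0.58. Arntl2 was lower at 6 h too, at -0.92. In normoxia the same list was lower at 3 h than at 1 h, by a median of -0.93, so a part of the difference lies in the normoxia libraries.

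Genes of glycogen metabolism, 4 in number, had medians of 1.25 at 3 h and 1.72 at 6 h; beside Ppp1r3c and Ppp1r3b these were the synthase Gys1, higher by 1.36 at 6 h, and Pgm2, higher by 1.35. Mat2a, which makes the methyl donor of the cell, was lower by -1.29 at 3 h and -1.90 at 6 h, and Amd1 of polyamine synthesis by -1.34 and -2.04; 82.8% of the words of Amd1 are shared with other genes. Genes of growth arrest and endothelial mitogens, 5 tested, went both ways at 6 h, 2 higher and 3 lower, with a median of -1.04.

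Across 571 genes, which are not independent replicates, Spearman correlations of the log2 differences with GC content and transcript length lay between -0.180 and 0.180. Correlations between libraries across genes lay between 0.762 and 0.989, and no pair of libraries was identical.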
